A study of Equus asinus with 6 samples.

How the data were processed

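RNA from longissimus dorsi, the long muscle of the back, of Guangling donkeys (Equus asinus) aged 24 months was sequenced as 6 libraries. Per the labels, 3 libraries came from muscle of high intramuscular fat (IMF) content and 3 from muscle of low IMF content, and the tissue was frozen in liquid nitrogen soon after slaughter. The groups and the replicate numbers 1, 2 and 3 were taken from the sample titles. The IMF content itself, the sex of the animals and the library batch are not given in the sources used here, and the labels name 2 different sequencers. Beyond their listing as samples, nothing in the labels states that the libraries came from separate animals, so p-values measure the spread between these libraries.

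The deposited read counts per gene are whole numbers that the authors assigned before deposit. The submitters' processing notes name the aligner HISAT2 and the genome build mm9, which is a mouse build, whereas the gene names and protein descriptions in the deposited table are those of donkey and horse genes; which genome the reads were aligned to was therefore left open. The counter, its annotation, its treatment of strand and of reads shared between copies, and the test behind the deposited comparison are not given in the sources used here. The deposited FPKM values were count per gene length and total count, since the gene length implied by count and FPKM varied by a median of 0.186% (coefficient of variation) over the 6 libraries among 1936 genes above 20 FPKM in every library; they entered no test. The deposited ratio of high over low IMF (fold change), its log2 value and the deposited p-values with their adjusted forms are the authors' own comparison and were used only where the authors' deposited table is named. The counts in the 6 per-sample files equalled those of the series' table in every cell (0 cells differed), so a run on the per-sample counts, set out before the data were examined, did not arise.

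The table listed 20873 genes, each with at least 1 read over the 6 libraries. Of these, 14721 carried a symbol in the file and 876 carried a LOC number that was matched to a symbol by gene identifier in a RefSeq gene table of assembly EquAss-T2T_v2, which was used for names only. A further 4550 kept a LOC number and 726 an identifier only; the latter held 0.704% of all reads and stayed in the library sizes and tests. No coordinates are given, because the build behind the counts was left open. No mitochondrially encoded gene was listed, so the run without these genes did not arise. The libraries held 39083515, 47494157 and 39052998 assigned reads in high IMF replicates 1 to 3 and 46360965, 45617163 and 44313770 in low IMF replicates 1 to 3. A count of 3 reads, the upper limit that a count of 0 allows at 95% confidence, was 0.0632 to 0.0768 CPM (read count scaled to a common library total). This limit was computed on total reads without the normalization described below, unlike the CPM values of genes. It covers counting error only.

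Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 after trimmed-mean (TMM) normalization and the filterByExpr filter with its default settings, which kept 15933 genes holding 99.96% of reads. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values are relative to TMM-adjusted library sizes and are given as mean ± SD over 3 libraries; a fold is the fitted high over low ratio, or low over high where so stated. Gene lists of muscle, fat, metabolic and cell-type genes, 36 in number, were fixed before the data were examined; 34 had members in the table, and the lists of mitochondrially encoded and sex-linked genes had 0. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists; camera with an estimated correlation and fry were alternatives. The level of a list in a library is the median over its members of log2 CPM minus the gene's mean over the 6 libraries.

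Genes are named by a rule set before the data were examined: the genes of largest fold past the threshold, or, with fewer than 5 per direction, those of smallest p with a symbol, at least 1 CPM on average and no overlap between groups, up to 5 and said not to pass; up to 4 members of smallest p from each list; a fixed set of lipid, fibre and matrix genes (PLIN1, PLIN2, FABP4, ADIPOQ, LEP, FASN, SCD, PPARG, LPL, CD36, CPT1B, MYH7, MYH2, MYH1, COL1A1 and PDGFRA); and the 3 genes of highest mean CPM. MYH7 and MYH1 were not listed under these names. Myosin heavy chain genes are near-identical copies in a cluster, so counts of MYH2 are uncertain.

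The other settings set out before the data were examined were DESeq2 1.42.0 size factors in edgeR, library size only, no low-count filter, a stricter filter (mean of at least 1 CPM and 10 reads in at least 3 libraries, 13597 genes), the DESeq2 Wald test, limma-voom, the replicate number as a block, each library left out in turn, robust dispersion estimates, other thresholds, and the other list tests. Settings added after seeing the data were low IMF replicates 2 and 3 summed as 1 library, edgeR's newer quasi-likelihood with adjusted deviances, and DESeq2 on reduced sets of libraries.

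The procedures were tested on simulated data with the means, dispersions and library sizes of these 15933 genes for the comparison of high with low IMF, with 200 genes changed. edgeR recovered 4 of 50 genes changed by 1 on the log2 scale, 37 of 50 changed by 2, 42 of 50 changed by 3 and 48 of 50 changed by 4, with 10 calls among unchanged genes. DESeq2 recovered 15, 39, 47 and 49 of 50, with 60 calls among unchanged genes. Each simulated library was drawn independently, so the simulation held no nearly alike pair such as low IMF replicates 2 and 3. Camera called 5 of 5 lists of 25 genes raised by 0.5 on the log2 scale and 0 of 35 unchanged lists; members of the simulated lists varied independently, unlike real genes. Figures were drawn with matplotlib 3.10.9.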

Results

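Transcripts of longissimus dorsi muscle were counted in 6 libraries from Guangling donkeys, a Chinese donkey breed, aged 24 months. Intramuscular fat (IMF) is the fat stored between and within muscle fibres. Muscle of high IMF content was sampled in 3 libraries and muscle of low IMF content in 3. The high IMF libraries held 39083515, 47494157 and 39052998 assigned reads and the low IMF libraries 46360965, 45617163 and 44313770, and 18098 to 19090 genes had at least 1 read in a library. The transcripts of highest mean level were those of muscle creatine kinase (CKM), skeletal actin (ACTA1) and aldolase A (ALDOA). CKM measured 33500 ± 18200 CPM (read count scaled to a common library total; SD, n = 3) in high and 51580 ± 16200 in low IMF muscle, ACTA1 29140 ± 4230 and 35660 ± 4740, and ALDOA 17020 ± 12200 and 27260 ± 13400; for each of the 3 the groups overlapped.

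The comparison of high with low IMF muscle asked which transcripts differ with the fat content of the muscle. DGAT2, which makes triglyceride from diacylglycerol, measured 56.7 ± 19.3 CPM in high and 10.7 ± 2.48 in low IMF muscle (5.3-fold), and the matrix protein gene CILP measured 138.6 ± 45.7 and 28.1 ± 9.03 (4.92-fold). The glutamine transporter SLC1A5 (4.25-fold), the peptide hormone gene APLN (2.95-fold) and the stress-induced gene SESN2 (2.52-fold) also had all 3 high libraries above all 3 low libraries. On the opposite side, the metalloproteinase inhibitor TIMP4 measured 35 ± 4.69 CPM in high and 112.7 ± 14 in low IMF muscle (3.22-fold higher in low), and the clock gene PER1 131.2 ± 23.1 and 374.6 ± 16.6 (2.85-fold higher in low). SMPDL3A, TEKT5 and TMEM37 were 2.57-, 2.62- and 2.94-fold higher in low IMF muscle, again without overlap between the groups. These are the 5 genes of smallest p in each direction among those with separate groups, and none passed the threshold in edgeR. edgeR's quasi-likelihood test gave an adjusted p of 0.263 for DGAT2, TIMP4, SMPDL3A, PER1 and TEKT5 and at most 0.374 (SESN2) for the others.

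Among 15933 genes tested, edgeR called 0 genes higher and 0 lower in high IMF muscle at an adjusted p under 0.05, and limma-voom also called 0. At an unadjusted p under 0.05 edgeR had 1158 genes, 721 higher and 437 lower, where 797 are expected if the p-values of unchanged genes are uniform. Of the 1158 genes, 62.3% were higher. In the fit with library size only, 84.8% of the genes that reached an unadjusted p under 0.05 in that fit were higher, and this scaling shifted the median log2 fold of all genes from 0.01 to 0.15. The groups did not overlap for 2065 genes, or 13%, where chance gives 10% if all 6 libraries are interchangeable. Low IMF replicates 2 and 3 were nearly alike, which raises the share that chance gives. The raised share was not computed, so the 13% cannot be read as an excess. The DESeq2 Wald test called 194 genes, 114 higher and 80 lower. The authors' deposited table held 194 genes at an adjusted p under 0.05, all 194 of them shared with the DESeq2 run. Its log2 folds differed from those of the DESeq2 run by at most 0.00184, so it is no separate evidence. The table marked 103 genes as up and 64 as down with an absolute log2 fold of at least 1.01. In that table the adjusted p was 8.77e-09 for DGAT2, 1.96e-07 for CILP, 1.49e-10 for TIMP4 and 2.11e-08 for PER1. The DESeq2 count moved with single libraries: it was 301 without high IMF replicate 1, 130 without high IMF replicate 2, 635 without high IMF replicate 3, 424 without low IMF replicate 1, 63 without low IMF replicate 2 and 79 without low IMF replicate 3. Leaving out high IMF replicate 1 gave 0 higher and 3 lower genes in edgeR.

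Of the 34 gene lists with members in the table, 8 were higher and 8 lower in high IMF muscle by camera with its preset correlation. With an estimated correlation 0 lists passed (adjusted p = 0.296 to 0.737 over these 16), and 0 passed fry's directional test. Without high IMF replicate 2 or without low IMF replicate 1 the number of higher lists was 4, and without low IMF replicate 2 the number of lower lists was 5. With library size only, which moved the median of all genes from 0.01 to 0.15, the 16 calls held while the list medians moved up with that of all genes, as from -0.18 to -0.06 for ribosomal proteins and from -0.27 to -0.09 for endothelial genes. In edgeR no list member passed the adjustment over all genes. Adjusted over the list alone, 7 lists had 1 member each past the threshold and the other 27 had 0. In the DESeq2 run some members passed over all genes. Among the higher ones were DGAT2 (adjusted p = 8.67e-09), GBE1 (0.00472), HK2 (0.00727), BTG2 (0.0141), EGR3 (0.0334), CXCL10 (0.0334) and RELB (0.0494). Among the lower ones were PER1 (2.11e-08), FLT1 (0.000663) and KLF15 (0.00129).

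Genes of triglyceride synthesis and the lipid droplet were higher in high IMF muscle as a list (camera adjusted p = 0.00475; adjusted p = 0.393 with an estimated correlation). Of 29 members tested, 19 had a positive log2 fold, 7 of them with an unadjusted p under 0.05, and none was lower at that level. The median log2 fold was only 0.18, below the mean of 0.54. The list's levels were 0.11, 0.02 and 0.04 in the high and -0.1, 0.01 and -0.04 in the low IMF libraries. DGAT2 passed when adjusted over the list alone. GPAM, which starts glycerolipid synthesis, measured 118.8 ± 91.5 CPM in high and 45.0 ± 4.26 in low IMF muscle, and LPIN2, a phosphatidate phosphatase, 11.6 ± 2.86 and 6.19 ± 1.18; neither passed. Without high IMF replicate 2 the log2 fold of GPAM was 0.56 in place of 1.4. The list's adjusted p was 0.0504 without low IMF replicate 1. The fatty acid synthesis list did not pass (adjusted p = 0.0971), though 6 of its 23 members were higher at an unadjusted p under 0.05 and none was lower. The desaturase SCD measured 154.5 ± 149 CPM in high and 11.7 ± 4.47 in low IMF muscle (13.2-fold). Its adjusted p was 0.51 in edgeR and 0.0328 in the authors' deposited table. The libraries measured 131.1, 313.7 and 18.8 CPM against 6.59, 14.9 and 13.6 CPM, and without high IMF replicate 2 the log2 fold of 3.73 was 2.67. Fatty acid synthase (FASN) measured 134.9 ± 59.5 and 71.8 ± 3.18 CPM. Its high IMF replicate 3 (68.4 CPM) lay below every low library. Fatty acid uptake and transport did not pass as a list (adjusted p = 0.293). CD36, a fatty acid transporter, measured 145.3 ± 21.6 CPM in high and 243.8 ± 28.5 in low IMF muscle without overlap. Its adjusted p was 0.51 in edgeR and 0.0419 in the authors' deposited table. Lipoprotein lipase (LPL) measured 225.5 ± 107 and 143.7 ± 54.3 CPM.

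Adipocyte markers were higher as a list (16 members tested, 11 with a positive log2 fold, median 0.91, camera adjusted p = 0.00876; adjusted p = 0.659 with an estimated correlation). High IMF replicate 2 decided this call. The list's median level on the log2 scale was 0.37, 1.45 and -0.55 in high IMF replicates 1 to 3 and -0.66, 0.11 and -0.08 in low IMF replicates 1 to 3. High IMF replicate 3 thus lay below low IMF replicates 2 and 3. Without high IMF replicate 2 the list's median log2 fold was 0.02 with an adjusted p of 0.384. Without low IMF replicate 1 the adjusted p was 0.0566. The lipid droplet coat gene PLIN1 measured 28.6, 108.0 and 7.53 CPM in the high and 1.56, 20.9 and 15.5 in the low IMF libraries. The adipokine ADIPOQ measured 30.3, 165.1 and 5.97 CPM against 3.02, 49.8 and 36.6, and its log2 fold of 1.17 became -0.72 without high IMF replicate 2. The lipogenic regulator THRSP measured 62.5 ± 76.9 CPM in high and 2.2 ± 1.79 in low IMF muscle (28.6-fold) without overlap between the groups. The lipid droplet proteins CIDEA (6.55-fold) and CIDEC (5.28-fold) were higher on average with overlap. None of the 3 passed in edgeR. In the DESeq2 run CIDEA passed (adjusted p = 0.044), and THRSP (0.0561) and CIDEC (0.127) did not. High IMF replicate 2 raised the folds of all 3 genes. Without it the log2 fold of THRSP was 3.06 in place of 4.84, that of CIDEA 1.47 in place of 2.71 and that of CIDEC 1.19 in place of 2.4. Leptin (LEP) measured 6.7 ± 8.32 and 0.923 ± 0.818 CPM, with 16.2 CPM in high IMF replicate 2, and the fatty acid carrier FABP4 76.8 ± 36.6 and 109.5 ± 17.7 CPM. The lipid droplet gene PLIN2 measured 70.3 ± 24.7 and 56.1 ± 28.0 CPM.

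**Figure D1:**
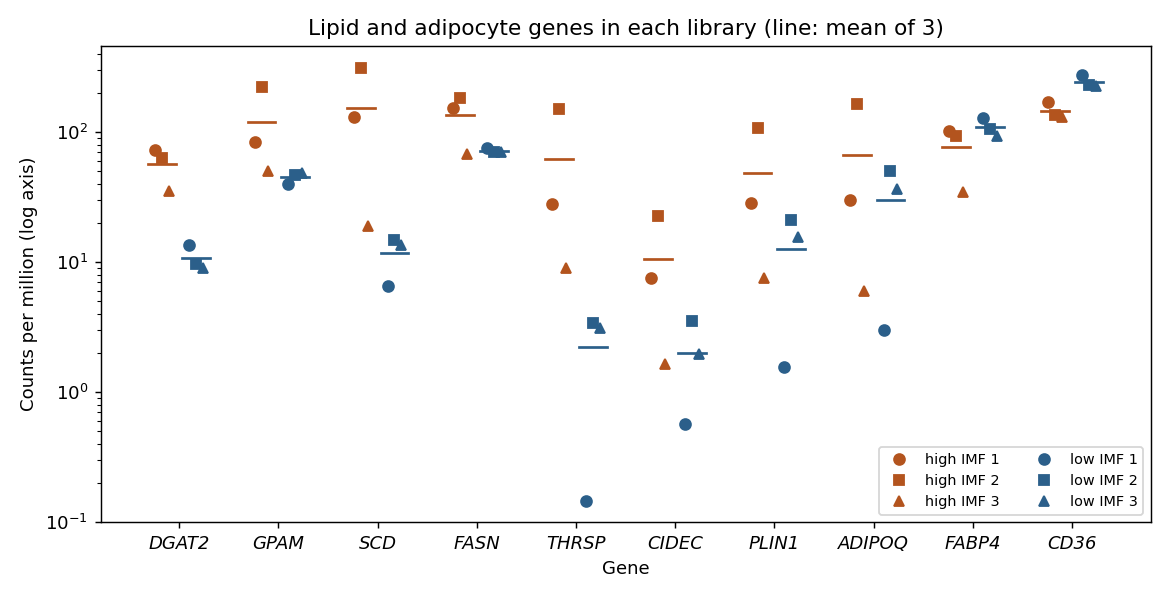
Scaled read counts (CPM, log axis) of 10 lipid and adipocyte genes in each library, with symbols for replicates, colours for the groups and a line at the mean of 3 libraries. DGAT2 and CD36 show separate groups, whereas for ADIPOQ and PLIN1 high IMF replicate 2 is the highest library (165.1 and 108.0 CPM) and high IMF replicate 3 lies below low IMF replicates 2 and 3.

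Adipogenic regulators did not pass as a list (camera adjusted p = 0.0605), with 3 members higher and 3 lower at an unadjusted p under 0.05. KLF15, a transcription factor of adipogenesis and amino acid breakdown, measured 41.9 ± 16.8 CPM in high and 113.8 ± 12.3 in low IMF muscle, and it passed when adjusted over the list alone. DLK1 and WNT10B, both known as inhibitors of adipogenesis, measured 7.67 ± 2.84 and 2.65 ± 0.962 CPM, and 2.11 ± 1.08 and 0.481 ± 0.288 CPM, in high and low IMF muscle. Neither passed in edgeR, and both passed in the DESeq2 run (adjusted p = 0.0294 and 0.0465). The adipogenic receptor PPARG measured 6.17 ± 3.5 and 5.49 ± 0.464 CPM.

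Both immune cell lists were higher by camera with the preset correlation, and no member passed in edgeR. In the DESeq2 run 1 member of each passed, MZB1 of the lymphocyte list (adjusted p = 0.044) and SPI1 of the myeloid list (0.0375). The lymphocyte list had 17 of 20 tested members with a positive log2 fold and a median of 1.48 (camera adjusted p = 1.08e-08; adjusted p = 0.545 with an estimated correlation). The macrophage and myeloid list had 20 of 24 with a median of 1.09 (camera adjusted p = 5.38e-08; adjusted p = 0.641 with an estimated correlation). Both calls held without each library in turn, but without high IMF replicate 1 the median log2 fold was 0.78 for the lymphocyte and 0.38 for the macrophage list. High IMF replicate 1 had the highest level of both lists on the log2 scale (1.3 and 1.22). High IMF replicate 3 had a macrophage level of -0.53, below the low IMF libraries (-0.42 to -0.33). The T cell gene CD8B measured 0.964 ± 0.446 and 0.156 ± 0.101 CPM, with 0.0486 in low IMF replicate 3. That is below a count of 3 reads, which gives 0.0677 CPM there on total reads without the TMM adjustment. The T cell kinase ZAP70 measured 2.33 ± 0.602 and 0.671 ± 0.471 CPM, and the myeloid factor SPI1 6.04 ± 2.56 and 2.28 ± 0.22 CPM. TYROBP, a myeloid receptor adaptor, measured 7.56 ± 2.97 and 3.51 ± 0.299 CPM. The inflammatory and NF-kB list was also higher (19 of 23 members positive, camera adjusted p = 0.00109; adjusted p = 0.545 with an estimated correlation; 0.0979 without high IMF replicate 2). RELB measured 12.1 ± 0.683 and 6.59 ± 1.22 CPM and the chemokine CXCL10 7.77 ± 2.01 and 2.61 ± 1.37 CPM. At an unadjusted p under 0.05 in edgeR, 7 members of this list were higher and 1, NFKBIA, was lower. NFKBIA measured 46.8 ± 5.88 CPM in high and 71.2 ± 19.1 in low IMF muscle without overlap. Genes of the immediate early and heat shock response were higher as a list (29 of 35 positive, camera adjusted p = 2.9e-07; adjusted p = 0.641 with an estimated correlation). Low IMF replicate 1 was at a level of -1.28 and the other low libraries at 0.12 and 0.16, beside 0.44, 0.08 and 0.6 in the high libraries. Without low IMF replicate 1 the adjusted p was 0.0505. In this list EGR3 measured 100.2 ± 15.4 and 20 ± 15 CPM, BTG2 361.6 ± 281 and 61.2 ± 39.1 CPM, and IER2 137.1 ± 55.7 and 59.7 ± 30.2 CPM. The interferon response list did not pass (adjusted p = 0.459).

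Fibroblast and fibro-adipogenic progenitor genes were higher as a list (29 of 30 positive, median 0.61, camera adjusted p = 0.000506; adjusted p = 0.659 with an estimated correlation). So were genes of matrix remodelling (26 of 34 positive, median 0.38, camera adjusted p = 0.0125; adjusted p = 0.711 with an estimated correlation). The fibroblast genes had levels of 0.82 and 0.8 in high IMF replicates 1 and 2 and of -0.66 to 0.05 in the low IMF libraries, and high IMF replicate 3 was the lowest of the 6 libraries (-0.98). The medians were 0.27 and 0.22 without high IMF replicate 1, 0.25 and 0.24 without high IMF replicate 2 and 1.01 and 0.71 without high IMF replicate 3. Both calls were lost without high IMF replicate 1 (adjusted p = 0.331 and 0.704), without high IMF replicate 2 (0.108 and 0.307) and without low IMF replicate 1 (0.0505 and 0.682). Collagen COL1A1 measured 109.6 ± 68.7 and 41.0 ± 6.28 CPM, the stromal surface gene THY1 72.6 ± 33.3 and 32.2 ± 6.19 CPM, the lysyl oxidase LOXL1 11.5 ± 7.95 and 4.01 ± 0.931 CPM. PDGFRA, the receptor used to mark fibro-adipogenic progenitors, measured 23.1 ± 15.5 and 19.3 ± 9.71 CPM. TIMP3 lay on the other side, with 309.2 ± 62.4 CPM in high and 469.1 ± 29.1 in low IMF muscle.

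By camera with the preset correlation, endothelial genes were lower as a list. Of 22 endothelial genes tested, 18 had a negative log2 fold, 4 of them with an unadjusted p under 0.05 (camera adjusted p = 0.000158; adjusted p = 0.641 with an estimated correlation). Their levels were 0.25, -0.16 and -0.58 in the high and 0.27, 0.21 and 0.1 in the low IMF libraries, so that high IMF replicate 1 lay within the low IMF range. The median log2 fold of -0.27 was -0.1 without high IMF replicate 3, where the call was lost (adjusted p = 0.0806), and -0.52 without high IMF replicate 1. The receptor FLT1 measured 58.9 ± 10.7 CPM in high and 123.1 ± 5.88 in low IMF muscle and passed when adjusted over the list alone. The junction genes ESAM and CLDN5 measured 61.0 ± 8.38 and 90.5 ± 8.91 CPM, and 64.9 ± 4.91 and 96.9 ± 15.1 CPM. Smooth muscle and pericyte genes were lower as a list (12 of 18 negative, camera adjusted p = 0.00809; adjusted p = 0.641 with an estimated correlation). The member of smallest p, the potassium channel gene KCNJ8, lay the other way, with 16.4 ± 3 CPM in high and 9.48 ± 0.533 in low IMF muscle without overlap, and did not pass. With overlap between the groups, smooth muscle myosin MYH11 measured 52.0 ± 33.3 and 218.4 ± 119 CPM and TAGLN 112.6 ± 19.7 and 203.0 ± 80.9 CPM. MYH11 passed in the DESeq2 run (adjusted p = 0.0191) and TAGLN did not (0.305). The levels of the smooth muscle list were -0.05, 0.02 and -0.42 in the high and -0.28, 0.29 and 0.23 in the low IMF libraries, so that low IMF replicate 1 lay below high IMF replicates 1 and 2. The adjusted p was 0.231 without high IMF replicate 3, 0.0813 without low IMF replicate 2 and 0.0533 with low IMF replicates 2 and 3 summed.

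Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, were lower as a list: 75 of 77 had a negative log2 fold with a median of -0.25, and none reached an unadjusted p under 0.05 (camera adjusted p = 4.29e-08; adjusted p = 0.659 with an estimated correlation). The call held without each library in turn, but the median was -0.14 without high IMF replicate 1, -0.12 without high IMF replicate 2 and -0.62 without high IMF replicate 3. High IMF replicates 1 and 2 were at -0.42 and -0.43, whereas high IMF replicate 3, at 0.39, was the highest of the 6 libraries. In the same 3 libraries the fibroblast list was at 0.82, 0.8 and -0.98 and the matrix list at 0.64, 0.53 and -0.72. NDUFA5 measured 118.8 ± 31.4 and 167.7 ± 14.1 CPM and NDUFS8 151.6 ± 44.8 and 211.5 ± 7.45 CPM. The tricarboxylic acid cycle list was lower too (22 of 23 negative, camera adjusted p = 0.0203; adjusted p = 0.711 with an estimated correlation), with IDH3B at 118.1 ± 27.8 and 149.8 ± 18.5 CPM. Its call was lost without high IMF replicate 1 (adjusted p = 0.331), without high IMF replicate 2 (0.488), without low IMF replicate 2 (0.146), without low IMF replicate 3 (0.0679) and with low IMF replicates 2 and 3 summed (0.108). Cytosolic ribosomal protein genes were lower by a median log2 fold of -0.18, with 81 of 83 negative (camera adjusted p = 2.77e-06; adjusted p = 0.659 with an estimated correlation). RPS27 measured 238.6 ± 10.4 and 311.7 ± 58.0 CPM. Fatty acid oxidation did not pass (adjusted p = 0.459; median log2 fold 0, mean -0.08), and CPT1B, the muscle carnitine palmitoyltransferase, measured 158.4 ± 66.8 and 132.6 ± 8.55 CPM.

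**Figure D2:**
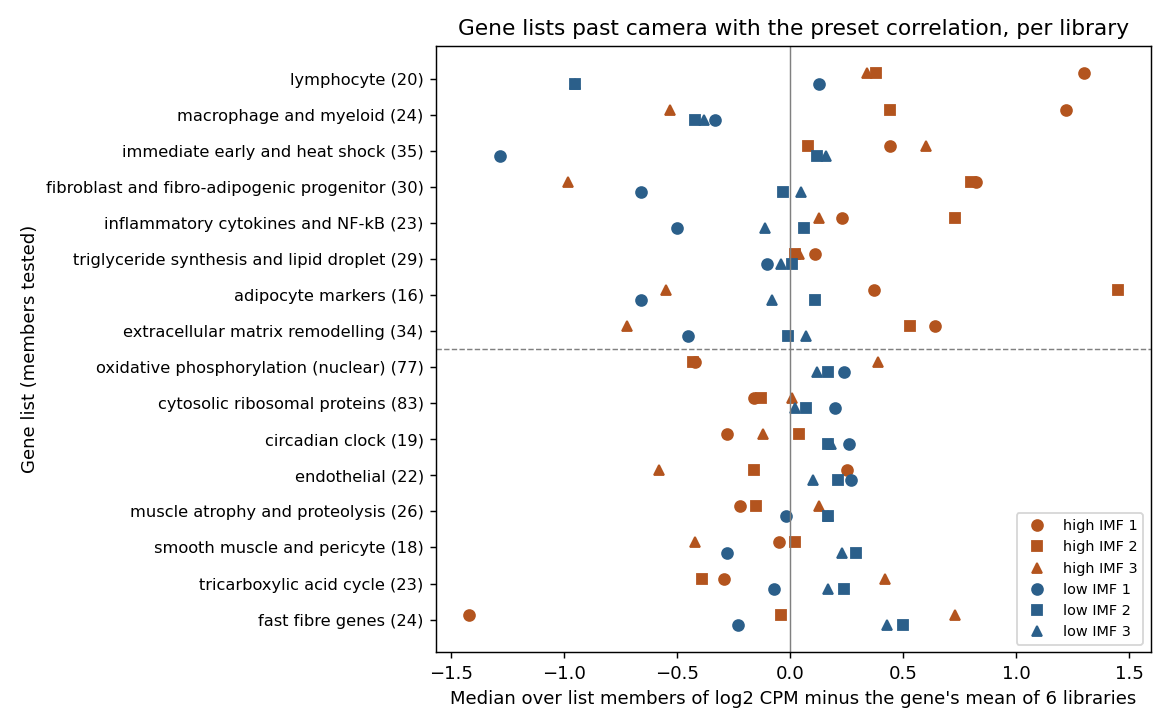
Level of the 16 gene lists that passed camera with the preset correlation, in each library, as the median over members of log2 CPM minus the gene's mean of the 6 libraries; colours mark the groups, symbols the replicates, and the dashed line parts the 8 higher from the 8 lower lists. For oxidative phosphorylation high IMF replicate 3 lies at 0.39, above the low IMF libraries, and for adipocyte markers high IMF replicate 2 lies at 1.45.

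Fibre type genes split the libraries across the groups. Fast fibre genes were lower as a list by camera (adjusted p = 0.0399; adjusted p = 0.737 with an estimated correlation), with a median log2 fold of -0.26 but a mean of 0.04. Their level was -1.42 in high IMF replicate 1, 0.73 in high IMF replicate 3 and 0.5 and 0.43 in low IMF replicates 2 and 3. Without high IMF replicate 1 the median turned to 0.07 (adjusted p = 0.238). The call was also lost without high IMF replicate 2 (0.0979), low IMF replicate 2 (0.182) or low IMF replicate 3 (0.133) and with low IMF replicates 2 and 3 summed (0.156). Slow fibre genes did not pass (adjusted p = 0.62; median -0.04, mean 0.17, test direction lower), with levels of 0.66 in high IMF replicate 1, 0.43 in low IMF replicate 1 and -0.39 to -0.14 in the other 4 libraries. The fast myosin MYH2 measured 14430 ± 8870 and 18190 ± 4850 CPM. SMTNL1, a contraction regulator of fast fibres, measured 407.5 ± 75.2 and 703.5 ± 68.2 CPM without overlap. It was the 1 fast fibre member lower at an unadjusted p under 0.05 in edgeR, and 1 member, PVALB, was higher. SMTNL1 passed in the DESeq2 run (adjusted p = 0.0401) and PVALB did not (0.534). PVALB measured 7.73 ± 7.35 and 0.186 ± 0.165 CPM with overlap. The first principal component, with 33.1% of the variance, set high IMF replicate 1 and low IMF replicate 1 apart from the other libraries.

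Circadian clock genes were lower as a list in high IMF muscle (14 of 19 negative, camera adjusted p = 5.86e-05; adjusted p = 0.296 with an estimated correlation). Their levels were -0.28, 0.04 and -0.12 in the high and 0.26, 0.17 and 0.18 in the low IMF libraries. With the preset correlation the call held without each library in turn (camera adjusted p = 8.46e-06 to 0.00155). PER1 passed when adjusted over the list alone. CIART measured 32.2 ± 11.1 and 61.7 ± 1.35 CPM, and CRY2 117.4 ± 38.9 and 186.0 ± 25.2 CPM. The muscle atrophy and proteolysis list was lower by camera (16 of 26 negative, adjusted p = 0.00475; adjusted p = 0.545 with an estimated correlation; 0.0613 without high IMF replicate 1). Its median log2 fold of -0.15 was 0.01 with library size only, where the median of all genes moved from 0.01 to 0.15 and the list call held (adjusted p = 0.00611). The median was -0.25 without high IMF replicate 3 and -0.23 without low IMF replicate 1, and the levels crossed the groups, with high IMF replicate 3 at 0.13 and low IMF replicate 1 at -0.02. KLF15 passed in this list too when adjusted over the list alone, and FOXO1, a transcription factor of the fasting response, measured 22.4 ± 2.38 and 30.8 ± 1.17 CPM. Insulin and IGF signalling did not pass (camera adjusted p = 0.0971), though its receptors IGF1R (30.6 ± 1.54 and 53.3 ± 12.2 CPM) and INSR (41.1 ± 1.72 and 55.0 ± 4.92 CPM) had separate groups. Glycolysis and glycogen did not pass (adjusted p = 0.725). The glycogen branching enzyme GBE1 measured 119.1 ± 10.8 and 60 ± 11.2 CPM and passed when adjusted over the list alone, and hexokinase HK2 measured 33.4 ± 19.1 and 9.83 ± 2.02 CPM.

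The remaining lists did not pass camera. The adjusted p was 0.0667 for Schwann cell and nerve genes, 0.0907 for lipolysis, 0.0971 for proteasome subunits, 0.326 for erythroid genes, 0.459 for cholesterol synthesis, 0.474 for sarcomere core and for cell cycle genes and 0.633 for AMPK and PGC-1 signalling. It was 0.559 for hypoxia and unfolded protein genes, of which SESN2 passed when adjusted over the list alone, and 0.967 for myogenic and satellite cell genes, whose median (0.05) differed in sign from the mean (-0.05) and the test. Fry's mixed test, which asks whether members change in either direction, passed for 6 lists.

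Libraries differed in ways that the groups do not describe. Low IMF replicates 2 and 3 differed by a median absolute log2 ratio of 0.077 over 8089 genes, whereas the other pairs differed by 0.214 to 0.405. Their median chi-square per gene was 1.98, where counting noise alone gives 0.455 and the other pairs gave 10 to 24.1, so they differed by more than sampling noise. They were kept as 2 samples, as listed, but this difference does not show that they came from separate animals. The SDs of the low IMF group and the p-values may therefore rest on fewer animals than libraries. With their counts summed as 1 library, an alternative chosen after seeing the data, edgeR called 0 genes, DESeq2 33 higher and 39 lower, and camera 8 higher and 5 lower lists. Low IMF replicate 1 alone had reads on a gene described as a Y-linked copy of EIF2S3 (2383 reads, against 0 in each of the other 5 libraries, where 3 reads are the upper limit that a count of 0 allows). This gene was singled out after its values were seen.

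**Figure D3:**
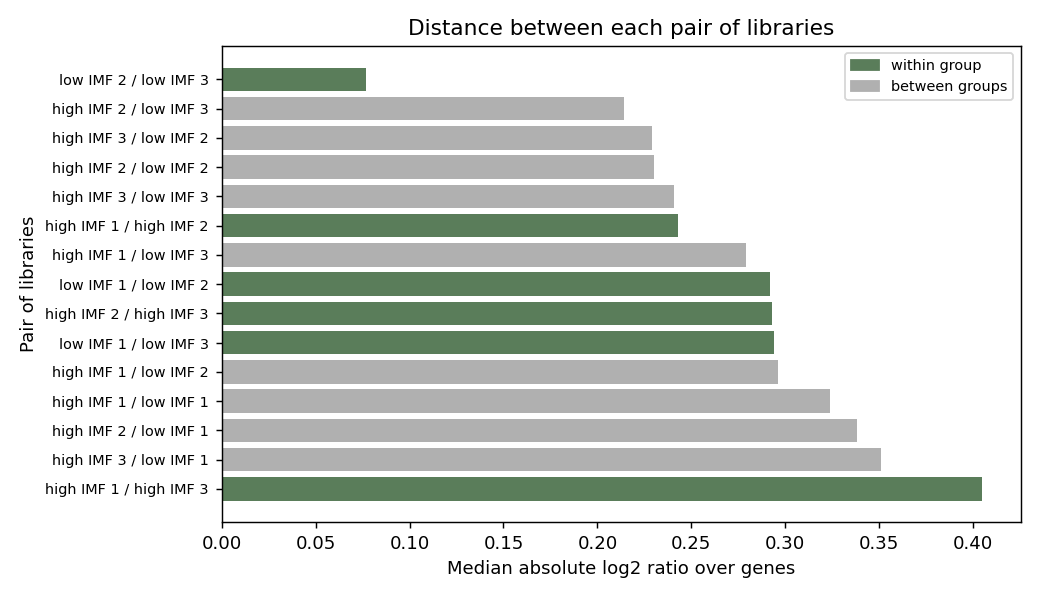
Median absolute log2 ratio between each pair of the 6 libraries over 8089 genes; longer bars mark less similar pairs, and colours tell pairs within a group from pairs between groups. Low IMF replicates 2 and 3 lie at 0.077 and the next pair, high IMF replicate 2 with low IMF replicate 3, at 0.214.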

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

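Tests on low IMF replicates 2 and 3 summed, on edgeR's newer quasi-likelihood and on DESeq2 with fewer libraries were chosen after the data were seen. edgeR called 0 genes in both directions under DESeq2 size factors, library size only, no or a stricter filter, robust dispersions, the newer quasi-likelihood and the summed libraries, and limma-voom called 0. A fold minimum added to the main fit could only leave 0 and says nothing more. Leaving out single libraries gave 0 higher genes throughout and 0 to 3 lower genes, the 3 being without high IMF replicate 1. An unadjusted p under 0.05 with a log2 fold of at least 1 gave 449 higher and 161 lower genes, since it drops the adjustment. DESeq2 gave 114 higher and 80 lower. With low IMF replicates 2 and 3 summed it gave 33 and 39, of which 60 were among the 194. Without high IMF replicates 1, 2 and 3 it gave 150 and 151, 61 and 69, and 401 and 234. Without low IMF replicates 1, 2 and 3 it gave 269 and 155, 29 and 34, and 43 and 36. The cause of these moves was not tested beyond the tests on low IMF replicates 2 and 3 under other observations. With single libraries left out 4 to 11 gene lists were higher and 5 to 10 lower, against 8 and 8. With low IMF replicates 2 and 3 summed there were 8 higher and 5 lower lists. With all 6 libraries there were 0 and 0 with an estimated correlation or by fry, both of which allow for members that move together. With the replicate number as a block edgeR called 0 higher and 0 lower genes and 9 higher and 9 lower lists. Deviations of same-numbered libraries correlated across genes at 0.2, 0.15 and 0.02. This cannot decide whether the numbers mark pairs. Low IMF replicates 2 and 3 were nearly alike, and deviations from a group mean depend on each other. Not every library correlated best with its own (high IMF replicate 2 with low IMF replicate 3, 0.21). Directions of 6 named genes and of the fast fibre list turned with a library left out. Over these fits the log2 fold ran from -0.07 to 0.53 for CPT1B, -0.87 to 0.03 for MYH2, -0.72 to 1.75 for ADIPOQ, -0.41 to 0.45 for PPARG, -0.15 to 0.72 for PDGFRA and -0.05 to 0.57 for PLIN2. The median of fast fibre genes ran from -0.85 to 0.07. The cause was not tested. The other values of named genes kept their direction (1077 comparisons, and 37 that passed under DESeq2). The direction of the list test held otherwise for the 16 lists (166 kept their call and 57 lost it), and the median of the muscle atrophy list, which went from -0.15 to 0.01 with library size only, moved there with the median of all genes (0.01 to 0.15). Over all genes the biological coefficient of variation between libraries was 35.8%. Depth limits genes of few reads, such as CD8B with 0.0486 CPM in low IMF replicate 3. A count of 3 reads gives 0.0677 CPM there on total reads without the TMM adjustment. In the simulated comparison, whose libraries were drawn independently, edgeR recovered 4 of 50 genes changed by 1 on the log2 scale and 37 of 50 changed by 2.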

Other observations

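The tests of the likeness of low IMF replicates 2 and 3, of the split counts of genes and of a male animal were chosen after the results were seen; the split count of lists, the test of mixed-in reads and that of glucocorticoid-induced genes were written down before their values were seen.

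Gene Ontology terms of the deposited annotation were tested for enrichment among the DESeq2 calls, an analysis chosen after seeing the data. Of 1979 terms with 10 to 500 members, 0 passed among 100 higher and 0 among 61 lower annotated genes, against a background of 13698 annotated genes with a DESeq2 adjusted p. The closest was extracellular space, with 13 of the higher genes where 3.39 are expected (one-sided hypergeometric test, adjusted p = 0.0641), among them the complement component C3, APLN, CXCL10, the lectin LGALS1 and the lactoferrin gene LTF. Inflammatory response came next, with 8 genes where 1.53 are expected (adjusted p = 0.147), among them RELB and CXCL10.

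Low IMF replicates 2 and 3 were far more alike than any other pair. A single library deposited in duplicate is argued against by a median chi-square per gene of 1.98, where counting noise alone gives 0.455. Membership of the low IMF group was tested by the distance of low IMF replicate 1, and 2 high IMF libraries were closer to both than it was. Low IMF replicate 1 alone had reads on the Y-linked copy of EIF2S3 and may lie apart for another reason. This test therefore cannot exclude group membership. A candidate explanation is that both come from 1 animal or from adjacent tissue: 0 genes were on in one (at least 50 reads) and off in the other (at most 1 read), where other pairs without low IMF replicate 1 had at least 11. Related animals or shared handling would also lower this number and stay open, as does the labels' listing of separate samples.

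DESeq2 called 194 genes and edgeR 0. With low IMF replicates 2 and 3 summed, DESeq2 called 72, fewer than without any one of the other 4 libraries (130 at least), so the likeness of this pair may have narrowed the spread that DESeq2 worked with. The 3 against 3 design makes 10 splits, too few for a share under 0.05. As many edgeR genes at an unadjusted p under 0.05 came from 2 of the 10 (1158 in the real split, 93 to 1864 in the others). As many DESeq2 calls came from 2 of the 10 (highest other 311, from high IMF replicates 1 and 2 with low IMF replicate 1 against the rest) and as many lists past camera from 2 of the 10 (16 in the real split, highest other 17). The splits are not alike, because some part the nearly alike low IMF replicates 2 and 3. Splits that part them gave 0 to 23 DESeq2 calls and 93 to 825 unadjusted edgeR genes. Those that keep them together, like the real one, gave 63, 129 and 311 calls and 764, 999 and 1864 genes. Ranks of gene counts among all 10 thus make the real split look rarer than it is. For edgeR calls past the adjustment the real split and the highest other have 0, so that all 10 of the 10 match it by construction and this count says nothing. In the simulated comparison DESeq2 made 60 calls among unchanged genes and edgeR 10. Its libraries were drawn independently, without a nearly alike pair, so these numbers do not carry over to the real libraries.

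Reads on genes described as Y-linked copies of EIF2S3 (2383 reads) and EIF1AY (340 reads) were found in low IMF replicate 1 alone; a Y-linked copy of a heat shock factor had 12 reads there and 0 to 4 in the others. The Y-linked copy of EIF2S3 had 51.9% as many reads as EIF2S3 in that library, and 0% in the other 5. Reads mixed in from another male library at a small share would keep this under 10%, so they are argued against, though the value lies close to the bound of 50% set for that. A candidate explanation is that this animal is male and the other 5 libraries come from females; the labels give no sex, and the value of 51.9% rests on a single library. In all, 12 genes had at least 100 reads in this library and at most 2 in any other, and one of these rows carried the symbol TMSB4X (4761 reads, at most 1 elsewhere), so that row may hold a Y-linked copy. Sex would then differ within the low IMF group and in part between the groups. It stays untested as a source of the low IMF spread and of the high over low folds. List calls lost without low IMF replicate 1, such as those of the adipocyte and fibroblast lists, cannot be told apart from it.

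PER1, KLF15 and CEBPD, which glucocorticoids are known to raise, and the clock gene CIART were lower in high IMF muscle on average, and none passed in edgeR. Lower glucocorticoid signalling in the high IMF animals was put forward as a hypothesis and tested on 13 other genes known to be induced by glucocorticoids, chosen from general knowledge; KLF9 among them was also in the adipogenic regulator list. The median log2 fold was -0.22 with 7 of 13 negative, and camera with an estimated correlation gave p = 0.286, so the test could not decide. FKBP5 (-1.39), ZBTB16 (-0.64) and CDKN1C (-0.76) went the way the hypothesis needs, and SAT1 (0.97) and SLC38A2 (0.73) the opposite way on the log2 scale.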
